A study of Mus musculus with 112 samples.

How the data were processed

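Mouse 46C ESCs were sampled, per the labels, 2 h after nucleofection of 75 µM control (scrambled), U1 or U2 AMO or of 50 µM U1+U2 AMO, and a line carrying SNRNP70 with an auxin-inducible degron (AID) was sampled at 0 h and 4 h of IAA. Cells were taken whole or separated into chromatin, cytoplasm and nucleoplasm, and each fraction was mixed with spike-in RNA: lacZ and mCherry transcripts for total RNA, ERCC for polyA RNA and SLAM-seq. Total RNA was depleted of ribosomal RNA. For SLAM-seq, 2 h of IAA were followed by 3 h of IAA with 4-thiouridine, and the labels give chromatin as total RNA and the soluble fractions as polyA RNA. Of 112 samples in the series, 101 library columns of lncRNA values and 4 peak lists were used. TT-seq and Malat1 ChIRP samples were not analysed here. One column of values was not used, since its name gives no fraction, which left 2 control libraries for whole cells of the AMO set.

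Values for total and polyA RNA were FPKM made by the authors, per the file headers scaled to spike-in RNA in chromatin, cytoplasm and nucleoplasm and with no such scaling named for whole cells. SLAM-seq values were a signal made by the authors, per the file headers counts of reads with T>C changes scaled to spike-in RNA. SLAM-seq values stood on whole steps, from which reads were recovered in all 18 libraries: 24927 to 227237 per library (chromatin 99102 to 227237, cytoplasm 24927 to 46990, nucleoplasm 39498 to 89879), of which 99.78% to 100% lay within 0.1 read of a whole number. Peak lists carried a score deposited with each peak, what it scores not being given in the sources used here. Per the submitters' processing notes CASAVA, TopHat and Cufflinks with build mm10 served for RNA, and Bowtie2 and bedtools with mm9 for ChIP-seq. The notes also name TopHat2 2.0.11. Other versions, annotation and filters are not given in the sources used here. Read depth of the FPKM libraries is not given either, so precision rests on the spread between libraries. The library kit was directional per the labels, but whether values count 1 strand is not given, so Tsix and Xist, or other overlapping pairs, may share signal.

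The 3 or 2 entries with a shared identifier were left out of the total and polyA tables, which left 1279 lncRNAs for AMO and for AID total RNA, 1246 for polyA RNA and 492 for SLAM-seq. Values were taken as log2 of the value plus the 10th percentile of values above zero (0.2 for AMO, 0.1 for AID total and polyA RNA, 8 for SLAM-seq). A lncRNA was tested where at least 3 of the libraries compared reached that amount. Groups were compared in limma 3.58.1 (R 4.3.3) with eBayes trend and Benjamini-Hochberg adjustment, threshold 0.05, 1 fit per fraction with all treatment groups of the table. The shift was the log2 change on chromatin minus the mean of the changes in cytoplasm and nucleoplasm (whole cells for polyA RNA), from 1 fit over these fractions, and the baseline was the chromatin level minus the soluble mean in control AMO cells or 0 h AID cells. No replicate block was used, because the labels do not say that a number marks a shared culture. They also do not say that replicates came from separate cultures, so p-values measure spread between these samples, which may be technical. These comparisons, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

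In each chromatin and shift comparison the rule named the 5 largest rises and falls past adjusted p 0.05 with no overlap of the chromatin libraries and a mean at or above the median of the lncRNAs tested. It named 3 of each in other fractions and up to 4 members per list that passed adjusted p 0.05. A standing set was named whether it passed or not, including Malat1, Neat1, Meg3, Rian, Kcnq1ot1, Tsix, Xist, Firre, Lncenc1, Tug1, Gas5, Snhg1, Pvt1 and Dleu2. The text gives part of these. Lists were nuclear-retained lncRNAs, snoRNA hosts, microRNA hosts, spliced cytoplasmic lncRNAs, ESC lncRNAs (Lncenc1, Panct2 and part of the Platr genes), imprinted lncRNAs, X-inactivation lncRNAs, lncRNAs of differentiated cells, small structured noncoding RNAs, and symbol patterns (opposite-strand, Gm, Rik, Snhg, Mir with hg, assembled lincRNA loci). The ESC list left out some Platr genes that were measured, among them Platr17 and Platr21, so its counts are not those of all Platr genes. Some genes are in several lists. They were tested with limma camera at a preset correlation of 0.01 for at least 5 members, adjusted over lists within a contrast, with an estimated correlation as an alternative. Overlaps were tested with a one-sided Fisher exact test. It takes lncRNAs as independent, which those read in the same libraries are not, so its p-values may be too low. For U1 and U2 AMO, which share controls, 100 simulated pairs of unchanged groups were compared. After the data had been seen 100 more were added, in which libraries kept the deviation of their replicate number. Positions are those of the same symbol on GRCm38 and were found for 584 of 1625 symbols. Peaks were compared with bedtools 2.31.1, at least 1 bp shared, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

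Alternatives were pseudocounts 10 times larger or smaller, no filter and a stricter one, libraries centred on their medians, eBayes without trend, 1 fit of all fractions, a replicate block, each soluble fraction alone, each library left out, and for peaks 50% reciprocal overlap, the peaks of higher score, and peaks merged within 1 kb. A fit with edgeR 4.0.16 (quasi-likelihood) on recovered SLAM-seq reads and direct contrasts of U1 AMO with U2 AMO and of U1+U2 AMO with U1 AMO on chromatin were added after the data had been seen. Detection was tested on simulated data with 199 lncRNAs of 1251 changed in the U1 AMO chromatin design: 61.2% were found at a log2 change of 1 and 91.7% at 2, with 4.4% of calls false. For the AID design these were 68%, 88.1% and 5.5%, for polyA RNA 69.7%, 93.8% and 3%, for SLAM-seq 76.1%, 96.2% and 5.5%, and for the U1 AMO shift 34.7%, 78.8% and 7.4% and the AID shift 33.6%, 79.6% and 0.9%. With edgeR on SLAM-seq chromatin reads 91.3% and 100% were found with 0 false calls. Loss of SNRNP70 protein and block of the small nuclear RNAs were not measured in these files. No RNA library came from cells without the degron given IAA. What is called SNRNP70 loss below thus cannot be told apart from other effects of IAA treatment.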

Results

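The series followed long noncoding RNAs (lncRNAs) of mouse embryonic stem cells (ESCs) after block or loss of U1 snRNP, the particle that recognises 5′ splice sites. U1, U2 or both small nuclear RNAs were blocked with antisense morpholino oligonucleotides (AMOs) against a scrambled control AMO. In a second line, SNRNP70, a protein of U1 snRNP, was degraded through an auxin-inducible degron (AID) by 4 h of indole-3-acetic acid (IAA). Values of 1279 lncRNAs were read in 47 AMO libraries and in 24 AID libraries of total RNA, each set made of whole cells, chromatin, cytoplasm and nucleoplasm. Polyadenylated (polyA) RNA of the AID line covered 1246 lncRNAs in 12 libraries of whole cells and chromatin, and labelled RNA (SLAM-seq) 492 lncRNAs in 18 libraries of chromatin, cytoplasm and nucleoplasm. Single peak lists for RNA polymerase II (Pol II) phosphorylated at Ser2 or Ser5 were held at 0 h and 4 h. Every group had 3 libraries apart from whole-cell control AMO, with 2. Means ± SD below are FPKM of 3 libraries unless stated, and a change is on the log2 scale. Largest changes are those among lncRNAs named by a rule fixed in advance.

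In control cells, Gm26870 stood furthest towards chromatin among named lncRNAs, at 429 ± 205 FPKM on chromatin against 19.4 ± 4.1 in cytoplasm and 5.6 ± 2.1 in nucleoplasm of control AMO cells (log2 5.28, adjusted p = 8.50e-12). It also led in 0 h AID cells, at 80.7 ± 9.2 on chromatin against 0.373 ± 0.46 and 0.857 ± 0.27 (log2 7.15, adjusted p = 1.22e-09). The imprinted antisense RNA Kcnq1ot1 (log2 2.96, adjusted p = 1.12e-13 in control AMO cells; log2 4.77, adjusted p = 1.82e-12 in 0 h AID cells), the paraspeckle RNA Neat1 in control AMO cells (log2 2.70, adjusted p = 4.25e-11) and Tsix, the antisense partner of Xist (log2 2.02, adjusted p = 3.44e-07; log2 3.05, adjusted p = 5.63e-10), were higher on chromatin. The histone transcript Hist2h2bb lay on the soluble side, at 105 ± 32 on chromatin against 8044 ± 740.3 in cytoplasm and 351 ± 52 in nucleoplasm (log2 -4.03, adjusted p = 3.68e-16). Lncenc1, an ESC lncRNA (ENSMUSG00000078952.9; chromosome 13, 97434970 to 97497664), was near even in control AMO cells (log2 0.01, 0.968 adjusted; -0.474 after centring of libraries on their medians, the opposite sign) and lower on chromatin in 0 h AID cells (log2 -0.44, adjusted p = 0.00312). In limma, 757 lncRNAs were higher and 127 lower on chromatin than in the soluble mean in control AMO cells (median log2 1.10 over 1277; 616 and 234 after centring, median 0.62). In 0 h AID cells 878 were higher and 143 lower (median 1.87; 819 and 199 after centring, median 1.57). Both contrasts depend on the authors' scaling making fractions comparable, and 4 of 100 splits of the control AMO libraries, the real one included, gave as many calls.

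On chromatin, U1 AMO lowered Platr4, an ESC lncRNA of the pluripotency-associated transcript family (chromosome 3, 41487681 to 41493199), from 18.7 ± 1.8 to 4.43 ± 0.89 (log2 -2.04, adjusted p = 2.41e-05). Nespas, an antisense RNA of the imprinted Gnas locus, fell from 17.1 ± 1.9 to 4.39 ± 0.25 (log2 -1.91, adjusted p = 9.59e-06). Lncenc1 fell from 87.7 ± 3.3 to 36.7 ± 5.6 (log2 -1.26, adjusted p = 0.000225). Neat1 (chromosome 19, 5824708 to 5845480) fell from 82.0 ± 5.5 to 35.0 ± 3.9 (log2 -1.23, adjusted p = 0.000451). Tsix (ENSMUSG00000085715.1; chromosome X, 103431517 to 103484957) fell from 10.9 ± 1.2 to 3.86 ± 1.3 (log2 -1.51, adjusted p = 0.00101). Kcnq1ot1 fell from 6.55 ± 0.69 to 3.03 ± 0.52 (log2 -1.07, adjusted p = 0.00191). The microRNA host Dleu2 fell from 33.1 ± 4.0 to 14.9 ± 1.6 (log2 -1.14, adjusted p = 0.000115). Malat1, an abundant RNA of nuclear speckles (ENSMUSG00000092341.2), fell from 831 ± 140.0 to 506 ± 37 (log2 -0.70, adjusted p = 0.0158), but was 0.137 after centring, the opposite sign. The snoRNA host Gas5 fell from 388 ± 34 to 241 ± 17 (log2 -0.69, adjusted p = 0.00976), likewise with the opposite sign after centring (0.15), while another snoRNA host, Snhg12, rose from 175 ± 10.2 to 382 ± 27 (log2 1.12, adjusted p = 0.000542). Snhg1 (148 ± 11 with control AMO, 145 ± 13 with U1 AMO; log2 -0.03, adjusted p = 0.873; 0.805 and so opposite in sign after centring), Tug1 (log2 0.15, adjusted p = 0.39), Meg3 (log2 -0.41, adjusted p = 0.0835; 0.0112 with a replicate block, but 0.432 after centring, the opposite sign) and Rian (log2 -0.19, adjusted p = 0.307, but 0.648 after centring, the opposite sign) did not pass. The largest falls by the fixed rule were Gm11457, from 3.31 ± 0.64 to 0.423 ± 0.37 (log2 -2.74, adjusted p = 0.00182), Gm13663 (log2 -2.49, adjusted p = 0.00248), Gm44983 (log2 -2.37, adjusted p = 0.000196) and Gm16104 (log2 -2.35, adjusted p = 0.000258). 1700056N10Rik also fell from 8.19 ± 1.2 to 1.5 ± 0.4 (log2 -2.32, adjusted p = 5.31e-05). The largest rises were Gm37262, from 3.03 ± 0.76 to 19.3 ± 3.9 (log2 2.60, adjusted p = 1.77e-05), Gm44130 (log2 1.73, adjusted p = 0.000196), Gm44045 (log2 1.65, adjusted p = 5.31e-05), Gm45354 (log2 1.58, adjusted p = 0.000262) and Gm42866 (log2 1.56, adjusted p = 0.00442). Of 1256 lncRNAs tested with limma, 651 fell and 64 rose (median log2 -0.80). In 818 of the 1256 the libraries of the groups did not overlap, against a share of 10% by chance for 3 against 3. That share holds for a single lncRNA. A scale difference common to whole libraries would separate many lncRNAs at once. Centring moved the median to 0.04 and left 226 rises and 145 falls, a balance that centring itself helps to set.

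**Figure D1:**
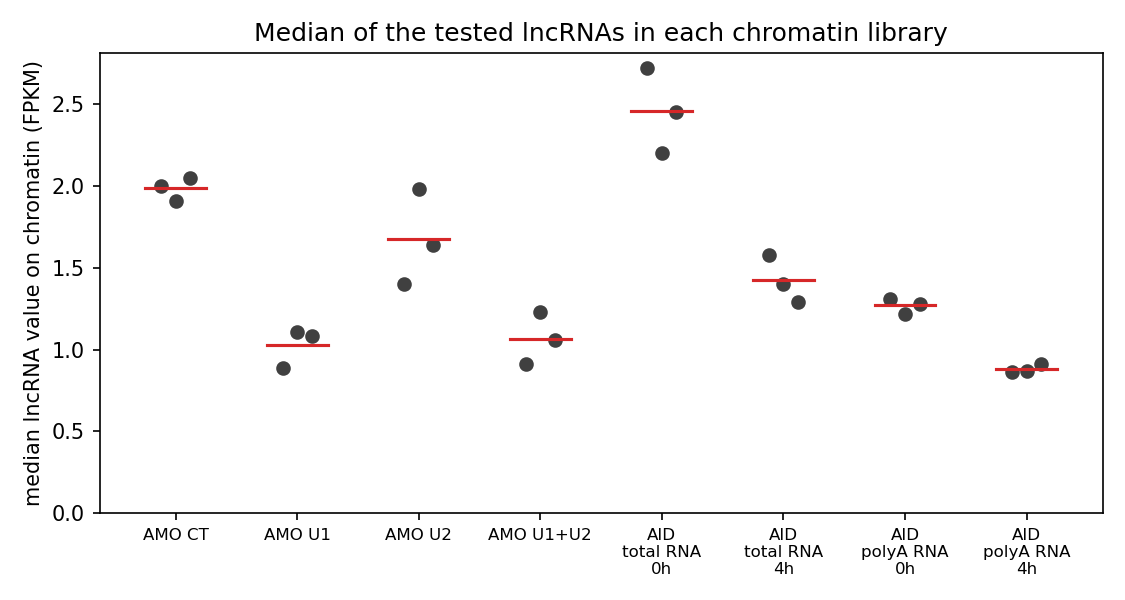
Median FPKM of the lncRNAs tested (vertical axis) in each chromatin library for control (CT), U1, U2 and U1+U2 AMO and for AID cells at 0 h and 4 h in total and polyA RNA; points are libraries and red lines are means of 3. The medians were 2, 1.91 and 2.05 in control AMO and 0.89, 1.11 and 1.08 in U1 AMO, 2.72, 2.2 and 2.45 at 0 h and 1.58, 1.4 and 1.29 at 4 h in total RNA, and 1.4, 1.98 and 1.64 in U2 AMO.

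Among lncRNA lists after U1 AMO, the ESC list had 12 of 18 members lower on chromatin and 0 higher, with 6 not passed (median -1.26). Those that fell included Platr6 (log2 -1.94, adjusted p = 0.000143), Platr27 (log2 -1.75, adjusted p = 0.000772) and Platr7 (log2 -1.68, adjusted p = 0.000451). Of 15 nuclear-retained lncRNAs 12 fell, 1 rose and 2 did not pass (median -1.14), with Mirg, of the imprinted Dlk1 to Dio3 domain, falling from 23.4 ± 2.8 to 8.42 ± 0.9 (log2 -1.45, adjusted p = 9.53e-05) and Pvt1, the neighbour of Myc, from 11.7 ± 2.2 to 5.52 ± 0.31 (log2 -1.04, adjusted p = 0.000345). Xist rose from 0.133 ± 0.04 to 0.757 ± 0.12 (log2 1.52, adjusted p = 0.000425), close to the lowest values measured. Of 12 snoRNA hosts Snhg12 rose, Snhg6 (log2 -0.97, adjusted p = 0.000503) and Gas5, opposite in sign after centring, fell, and 9 did not pass. MicroRNA hosts gave 6 falls of 8 (Mir22hg, log2 -1.12, adjusted p = 0.00379; Ftx, log2 -1.34, adjusted p = 0.00117), and imprinted lncRNAs 3 of 5 (Nespas, Mirg and Kcnq1ot1). Spliced cytoplasmic lncRNAs gave 1 rise (Snhg12) and 3 falls of 10 (Snhg6, with Gas5 and Dancr, both opposite in sign after centring). Differentiated-cell lncRNAs gave 4 falls of 8 (Mir124a-1hg, Miat, Sox2ot, and Halr1, opposite in sign after centring), and opposite-strand genes 16 falls of 37 (14 adjusted over the list alone; Prox2os, log2 -1.52, adjusted p = 0.00212; Lrrc75aos2, log2 -1.45, adjusted p = 0.000119). Gm-numbered genes gave 52 rises and 422 falls of 817, Rik genes 9 and 138 of 272, and Snhg-named genes 1 and 1 of 9. Tested with limma camera, relative to the other lncRNAs, no list passed. It gave adjusted p = 0.0889 for the ESC, nuclear-retained, snoRNA-host and Snhg-named lists and 0.167 for microRNA hosts, cytoplasmic and imprinted lncRNAs. It gave 0.463 for differentiated-cell and Gm genes and 0.874 for opposite-strand and Rik genes. After centring 4 lists passed: snoRNA hosts and Snhg-named genes (both 0.0138) and cytoplasmic lncRNAs (0.0185) were higher and the ESC list (0.0265) lower, but without centring each had 0.59 with an estimated correlation. Of the 4 X-inactivation lncRNAs measured, under the 5 needed for a test, Xist rose and Tsix, Ftx and Firre (log2 -0.77, adjusted p = 0.00744, but 0.068 after centring, the opposite sign) fell. Of 4 genes named Mir with the ending hg, Mir22hg, Mir124a-1hg (log2 -1.02, adjusted p = 0.00288) and Mir17hg (log2 -0.46, adjusted p = 0.0214, but 0.381 after centring, the opposite sign) fell and 1 did not pass. The lists of small structured noncoding RNAs and assembled lincRNA loci had 0 members in the tables.

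Away from chromatin, Gm37262 rose in every fraction of U1 AMO cells, from 0.287 ± 0.16 to 6.41 ± 2.1 (log2 3.75, adjusted p = 2.56e-06) in nucleoplasm, log2 2.88 in cytoplasm and 2.42 in whole cells (n = 2 controls). Gm42929 rose from 1.67 ± 0.92 to 16.7 ± 4.3 (log2 3.24, adjusted p = 0.0013) in cytoplasm, and Gm44130 in cytoplasm (log2 2.96) and nucleoplasm (3.33). Gm37795 fell in whole cells (log2 -2.15, adjusted p = 0.000187), cytoplasm (log2 -2.12, adjusted p = 0.00151) and nucleoplasm (log2 -1.91, adjusted p = 0.000489), and Sox2ot, which overlaps Sox2, fell from 4.92 ± 0.95 to 0.98 ± 0.66 (log2 -2.31, adjusted p = 0.0128) in cytoplasm. Snhg1 rose in cytoplasm (log2 0.90, adjusted p = 0.0243) and nucleoplasm (log2 1.32, adjusted p = 0.0178). In whole cells 78 lncRNAs rose and 90 fell of 1251 (median -0.21; 102 and 58 after centring, median -0.05; 70 calls without control library 1). In cytoplasm 49 rose and 42 fell of 1242, with 48, 47 and 44 calls without control library 1, control library 3 or U1 AMO library 3. In nucleoplasm 120 rose and 42 fell of 1142 (131 and 116 after centring).

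The shift, defined as the change on chromatin minus the mean change in cytoplasm and nucleoplasm, was largest by the fixed rule after U1 AMO for Gm28373 (log2 -2.69, adjusted p = 1.04e-05). Its level fell from 9.18 ± 0.72 to 5.13 ± 1.1 on chromatin and rose from 1.18 ± 0.38 to 5.78 ± 0.81 in cytoplasm and from 0.523 ± 0.16 to 2.02 ± 0.82 in nucleoplasm. C230096K16Rik (log2 -1.73, adjusted p = 0.000193) went from 18.9 ± 1.5 to 7.95 ± 0.45 on chromatin while its cytoplasmic mean was 6.01 ± 1.0 with control AMO and 9.84 ± 2.2 with U1 AMO. Gm16104 (log2 -2.03, adjusted p = 0.0177), Gm44017 (log2 -1.74, adjusted p = 0.0034), Gm45222 (log2 -1.72, adjusted p = 0.000475), Platr6 (log2 -1.45, adjusted p = 0.0044), Pvt1 (log2 -1.34, adjusted p = 0.00729), Gas5 (log2 -1.22, adjusted p = 0.00764), Snhg1 (log2 -1.14, adjusted p = 0.0112), Neat1 (log2 -1.07, adjusted p = 0.0226) and Lncenc1 (log2 -1.01, adjusted p = 0.00729) moved the same way, as did Kcnq1ot1 (log2 -0.82, adjusted p = 0.0278, but 0.018 after centring, the opposite sign). Malat1 (log2 -0.70, adjusted p = 0.11) and Tsix (log2 -1.08, adjusted p = 0.0552) did not pass. Of 1277 lncRNAs tested with limma 252 shifted away from chromatin and 1, 1700042O10Rik, named after its value was seen, towards it (median -0.66; 10 towards and 3 away after centring). Of the 252, 208 fell on chromatin, 44 rose in a soluble fraction and 6 did both; 194 fell on chromatin with no soluble call. Medians of the 252 were -1.28 on chromatin, -0.02 in cytoplasm and 0.10 in nucleoplasm. Leaving out control chromatin library 1, control chromatin library 3 or U1 AMO chromatin library 1 gave 148, 115 and 104 calls. No list passed camera, the ESC list with 7 of 18 members shifted away (8 adjusted over the list alone; adjusted p = 0.441).

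After U2 AMO, the snoRNA host Snhg1 (chromosome 19, 8723487 to 8726326) rose on chromatin from 148 ± 11 to 517 ± 13 (log2 1.80, adjusted p = 0.00014). Gas5 rose from 388 ± 34 to 865 ± 119 (log2 1.15, adjusted p = 0.00431). Snhg12 rose from 175 ± 10.2 to 384 ± 46 (log2 1.12, adjusted p = 0.00452). Gm45073 rose from 0.75 ± 0.27 to 5.1 ± 0.54 (log2 2.51, adjusted p = 0.00014). Gm15344 rose from 13.2 ± 1.6 to 40.2 ± 9.0 (log2 1.58, adjusted p = 0.00122). E230020D15Rik (log2 2.12, adjusted p = 0.000782) and Gm44553 (log2 1.39, adjusted p = 0.00955) rose as well. Neat1 fell from 82.0 ± 5.5 to 41.9 ± 6.8 (log2 -0.98, adjusted p = 0.0126). Dleu2 fell from 33.1 ± 4.0 to 17.5 ± 0.48 (log2 -0.90, adjusted p = 0.00429). Gm7265 fell from 7.93 ± 1.4 to 2.73 ± 0.19 (log2 -1.46, adjusted p = 0.000782), with Gm15903 (log2 -1.86, adjusted p = 0.00429), 2810405F17Rik (log2 -1.49, adjusted p = 0.00429), Platr21 (log2 -1.45, adjusted p = 0.00498) and Gm37321 (log2 -1.37, adjusted p = 0.0073) among the largest falls. Malat1 (513 ± 69.5 after U2 AMO; log2 -0.69, adjusted p = 0.0742; 0.0104 with a replicate block), Lncenc1 (log2 -0.59, adjusted p = 0.0763; 0.0041 with that block) and Tsix (log2 0.21, adjusted p = 0.749) did not pass. In limma 35 rose and 63 fell of 1256 (median -0.14; 100 and 47 after centring, median 0.09). With a replicate block the count was 189 instead of 98, and without control chromatin library 1 or 3 or U2 AMO library 1 or 3 it was 40, 51, 58 and 51. Relative to other lncRNAs by camera, snoRNA hosts were higher (3 rose, those above, 0 fell, 9 not passed; 5 rose adjusted over the list alone; adjusted p = 4.72e-06, but adjusted p = 0.124 with an estimated correlation). The same loss at adjusted p = 0.124 with an estimated correlation held for Snhg-named genes (2 rose, 0 fell of 9; 4 over the list alone; adjusted p = 2e-05), cytoplasmic lncRNAs (3 rose, 0 fell of 10; 0.000385), microRNA hosts (0 rose, 4 fell of 8, Mir17hg, Mirg, Mir124a-1hg and Dleu2; 0.00127) and the ESC list (0 rose, 3 fell of 18, Platr4, Platr6 and Platr14; 6 over the list alone; 0.00155). Nuclear-retained lncRNAs (0 rose, 3 fell of 15, Neat1, Mirg and Dleu2; 9 over the list alone; adjusted p = 0.00174, but adjusted p = 0.339 with an estimated correlation) and Rik genes (4 rose, 24 fell; 0.00645, but adjusted p = 0.373 with an estimated correlation) were lower, and Gm genes (26 rose, 27 fell; 0.00518, but adjusted p = 0.581 with an estimated correlation) higher. Imprinted (0.113), differentiated-cell (0.658) and opposite-strand genes (0.769) did not pass.

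In nucleoplasm of U2 AMO cells Gas5 rose from 88.2 ± 23 to 457 ± 67 (log2 2.40, adjusted p = 0.000317). Snhg1 rose from 51.0 ± 13 to 279.9 ± 43 (log2 2.47, adjusted p = 0.000243), behind Gm12981 (log2 3.08, adjusted p = 8.31e-05), Gm42748 (log2 3.01, adjusted p = 6.89e-06) and Gm43360 (log2 2.85, adjusted p = 5.22e-05). Whole cells had more Gm15344 (log2 2.38, adjusted p = 0.00456), E230020D15Rik (log2 2.13, adjusted p = 0.00307), Snhg1 (log2 1.23, adjusted p = 0.00307) and Gas5 (log2 1.07, adjusted p = 0.00508) and less Dleu2 (log2 -1.31, adjusted p = 0.00553). In cytoplasm Gm42929 (log2 2.36, adjusted p = 0.0226), Gm43360 (log2 1.62, adjusted p = 0.0269), Gas5 (log2 1.06, adjusted p = 0.0226), Gm42748 (log2 1.09, adjusted p = 0.0444) and 1110038B12Rik rose, the last from 375 ± 11 to 851 ± 76 (log2 1.18, adjusted p = 0.0226). Nucleoplasm gave 221 rises and 0 falls of 1142 in limma, with 375 at unadjusted p under 0.05 (median 0.45; 95 rises and 37 falls after centring, median -0.06). Its count was 142, 137 and 125 without control nucleoplasm library 2, control library 3 or U2 AMO library 1. Whole cells gave 28 rises and 16 falls (9, 0 and 29 calls without control library 1, control library 2 or U2 AMO library 1). Cytoplasm gave 5 rises and 11 falls (7 and 6 after centring; 0, 1, 0, 2 and 0 calls without control libraries 1, 2 and 3 and U2 AMO libraries 1 and 3).

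The shift after U2 AMO passed for 7 lncRNAs, all away from chromatin. Gm43360 (log2 -1.55, adjusted p = 0.0218) rose from 0.423 ± 0.076 to 4.32 ± 0.86 in nucleoplasm, whereas 5031425E22Rik (log2 -1.30, adjusted p = 0.0218) went from 15.7 ± 1.4 to 8.3 ± 1.0 on chromatin, and C230096K16Rik (log2 -1.19, adjusted p = 0.0261) and Gm42748 (log2 -1.14, adjusted p = 0.0218) shifted too. With limma 0 lncRNAs moved towards chromatin; 161 of all had unadjusted p under 0.05 (median -0.28; 2 towards and 1 away after centring). The count was 0 without control chromatin library 1, control chromatin library 3 or U2 AMO chromatin library 1, 3 without U2 AMO chromatin library 3 or U2 AMO nucleoplasm library 1, and 11 without control cytoplasm library 1. The ESC list had 0 members past the threshold, 4 adjusted over the list alone, and lay lower by camera (adjusted p = 0.0314, but adjusted p = 0.95 with an estimated correlation and 0.0872 after centring).

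A direct contrast of U1 with U2 AMO, which leaves out the control libraries, shifted Tsix (log2 -1.88, adjusted p = 0.0248; chromatin 13.1 ± 4.0 in U2 AMO and 3.86 ± 1.3 in U1 AMO), then Gm37932 (log2 -1.75, adjusted p = 0.0419), Gm45073 (log2 -1.47, adjusted p = 0.027), AI838599 (log2 -1.28, adjusted p = 0.0437), Gm45223 (log2 -1.24, adjusted p = 0.049) and Snhg1 (log2 -1.22, adjusted p = 0.0437). In limma 12 lncRNAs lay further from chromatin with U1 AMO and 0 nearer, with 214 at unadjusted p under 0.05 (median -0.35; 1 and 1 after centring). Leaving out U1 AMO chromatin libraries 1 to 3 gave 5, 2 and 5, U2 AMO chromatin libraries 1 to 3 gave 4, 0 and 1, and U1 AMO cytoplasm libraries 1 and 3 gave 31 and 5. U2 AMO cytoplasm libraries 2 and 3 gave 29 and 6, U1 AMO nucleoplasm libraries 1 to 3 gave 4, 30 and 4, and U2 AMO nucleoplasm libraries 2 and 3 gave 4 and 2. The shifts by U1 and by U2 AMO shared 6 falls of 252 and 7, against 1.4 expected (252 × 7 / 1277). Simulated unchanged groups with the same controls shared 0, but had only 0.11 and 0.09 calls on average, so they set no level for this count. Their correlation of 0.455 across genes, which are not independent replicates, was below the simulated 0.507, with covariance 0.122 against 0.144. Where simulated libraries kept the deviations of their replicate number, these were 0.501 and 0.083, so whether the shifts covary beyond the shared controls stays open. On chromatin 60 falls were shared, against 32.7 expected (651 × 63 / 1256), the simulated groups again having too few calls (0.04 each) to compare. After centring 29 falls (5.4 expected) and 43 rises (18 expected) were shared. The correlation was 0.402 against 0.508 simulated (0.498 with replicate numbers). The covariance was 0.155 against 0.078 (0.043), and these simulated values already hold what the shared controls give. Part of the excess of shared falls over the count expected may come from the shared controls.

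With U1+U2 AMO together, Gm37795 fell on chromatin from 23.2 ± 4.8 to 4.95 ± 0.86 (log2 -2.18, adjusted p = 1.57e-05). Neat1 fell from 82.0 ± 5.5 to 31.3 ± 8.0 (log2 -1.42, adjusted p = 0.000249). Lncenc1 fell from 87.7 ± 3.3 to 39.7 ± 5.5 (log2 -1.15, adjusted p = 0.000533). Gas5 fell from 388 ± 34 to 216 ± 16 (log2 -0.85, adjusted p = 0.00348), and Malat1 fell too (log2 -0.58, adjusted p = 0.0405, but 0.217 after centring, the opposite sign). Gm20548 (log2 -2.81, adjusted p = 0.000203), C78283 (log2 -2.24, adjusted p = 5.81e-05), Platr21 (log2 -2.23, adjusted p = 5.91e-05) and Gm13663 (log2 -2.18, adjusted p = 0.00634) were the other largest falls. Gm37262 rose from 3.03 ± 0.76 to 16.7 ± 4.4 (log2 2.38, adjusted p = 4.14e-05), and Gm45354 (log2 1.46, adjusted p = 0.000558), Gm44130 (log2 1.46, adjusted p = 0.000706), Gm44045 (log2 1.45, adjusted p = 0.000113) and Gm28791 (log2 1.36, adjusted p = 0.000223) followed. In limma 48 rose and 618 fell (median -0.74; 188 and 103 after centring, median 0.05). Against U1 AMO alone 0 lncRNAs passed in limma on chromatin, 43 having unadjusted p under 0.05 (median 0.02). Per the labels U1+U2 AMO was given at 50 µM and the other AMOs at 75 µM. Dose thus differed as well, and the lack of calls does not show that U2 block added nothing. The ESC list lay lower than other lncRNAs by camera (0 rose, 14 fell of 18; 15 over the list alone; adjusted p = 0.0323, but adjusted p = 0.818 with an estimated correlation and 0.0922 with a replicate block), while the nuclear-retained list (1 rose, 12 fell of 15; 0.181) and the others did not pass.

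Elsewhere in U1+U2 AMO cells Gm42929 rose in cytoplasm (log2 3.16, adjusted p = 0.00147) and Gm37262 (log2 3.38, adjusted p = 9.76e-06), Gm37522 (log2 2.84, adjusted p = 5.74e-06) and Gm43178 (log2 2.60, adjusted p = 5.74e-06) in nucleoplasm. Shifts included those of Gm43514 (log2 -2.70, adjusted p = 0.0387), Gm28373 (log2 -2.46, adjusted p = 5.63e-05), 2010110E17Rik (log2 -1.84, adjusted p = 0.0495), C230096K16Rik (log2 -1.77, adjusted p = 0.000122), Neat1 (log2 -1.34, adjusted p = 0.0142) and Pvt1 (log2 -1.09, adjusted p = 0.0332). Whole cells gave 78 rises and 67 falls (95 and 47 after centring; 71 and 82 calls without control library 1 or 2). Cytoplasm gave 34 and 68 (58 and 43 after centring; 54, 41, 62 and 62 calls without control library 1, control library 3, or U1+U2 AMO library 2 or 3). Nucleoplasm gave 90 and 78 (105, 107, 104 and 92 calls without control library 1 or 3 or U1+U2 AMO library 1 or 2). In limma 107 lncRNAs shifted away from chromatin and 0 towards it (median -0.50; 9 towards and 4 away after centring). Leaving out control chromatin library 1, control chromatin library 3, U1+U2 AMO chromatin library 1 or control nucleoplasm library 2 gave 45, 7, 34 and 64. Of the 107, 87 fell on chromatin and 20 rose in a soluble fraction. No list passed for this shift (ESC, adjusted p = 0.106).

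Degrading SNRNP70 for 4 h lowered Platr4 on chromatin from 35.3 ± 7.9 to 5.02 ± 1.5 (log2 -2.81, adjusted p = 4.19e-05). Nespas fell from 24.2 ± 2.3 to 6.03 ± 1.1 (log2 -2.0, adjusted p = 4.65e-05). Lncenc1 fell from 93.9 ± 14 to 48.4 ± 4.3 (log2 -0.95, adjusted p = 0.0011). Neat1 fell from 61.4 ± 16 to 28.0 ± 6.6 (log2 -1.13, adjusted p = 0.00231). Malat1 (chromosome 19, 5795690 to 5802672) fell from 1286 ± 119 to 697 ± 103 (log2 -0.89, adjusted p = 0.00463). Kcnq1ot1 (chromosome 7, 143213111 to 143296547) fell from 9.0 ± 1.2 to 4.21 ± 0.47 (log2 -1.08, adjusted p = 0.000923). Firre, an X-linked chromatin-associated RNA (chromosome X, 50563120 to 50635321), fell from 29.3 ± 0.75 to 13.9 ± 3.2 (log2 -1.09, adjusted p = 0.000853). Dleu2 fell from 13.8 ± 2.0 to 6.84 ± 0.34 (log2 -0.99, adjusted p = 0.00103). Meg3 (log2 -0.69, adjusted p = 0.00798) and Rian (log2 -0.64, adjusted p = 0.00652), neighbours in the imprinted Dlk1 to Dio3 domain, fell too, but had the opposite sign after centring (0.049 and 0.103). Gm43513 fell from 4.6 ± 0.6 to 0.4 ± 0.25 (log2 -3.34, adjusted p = 6.14e-05) and 4930461G14Rik fell too (log2 -3.10), with Gm16008 (log2 -3.06, adjusted p = 4.65e-05) and Gm44033 (log2 -2.96, adjusted p = 0.000428) the other largest falls. Snhg12 rose from 129 ± 11 to 321 ± 12 (log2 1.31, adjusted p = 0.00015). Snhg3 rose from 50.0 ± 4.1 to 85.7 ± 9.8 (log2 0.77, adjusted p = 0.00282). Gm37115 rose from 4.51 ± 0.79 to 11.3 ± 1.1 (log2 1.31, adjusted p = 0.000353), next to Gm45205 (log2 1.30, adjusted p = 0.00177), Gm12737 (log2 1.27, adjusted p = 0.00916) and Gm38336 (log2 1.26, adjusted p = 0.000912). Gas5 (282 ± 35 before, 328 ± 27 after; log2 0.22, adjusted p = 0.323), Snhg1 (log2 0.28, adjusted p = 0.169), Tug1 (log2 0.13, adjusted p = 0.574) and Tsix (log2 -0.28, adjusted p = 0.248, but 0.463 after centring, the opposite sign) did not pass. Of 1260 lncRNAs tested with limma 588 fell and 40 rose (median -0.65; 265 rises and 210 falls after centring, median 0.09). For 715 of the 1260 the libraries did not overlap, against 10% by chance for a single lncRNA, a share that a common library scale could also exceed.

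By camera, relative to other lncRNAs on chromatin of AID cells, the ESC list was lower, with 17 of 18 fallen, 0 risen and 1 not passed (median -1.62; adjusted p = 0.000133, but adjusted p = 0.476 with an estimated correlation). SnoRNA hosts were higher (4 rose, Snhg3, Snhg12, Snhg20 and Epb41l4aos, log2 1.64, adjusted p = 0.0148, Snhg6 and Rian, the latter opposite in sign after centring, fell, and 6 did not pass; median 0.20; adjusted p = 0.000376, but adjusted p = 0.476 with an estimated correlation), as were Snhg-named genes (3 rose, 1 fell of 9; 2 and 1 over the list alone; 0.00124) and cytoplasmic lncRNAs (2 rose, 2 fell of 10; 0.00319), both likewise at adjusted p = 0.476 with an estimated correlation. Dancr fell (log2 -0.72, adjusted p = 0.00682, but 0.027 after centring, the opposite sign). Nuclear-retained (0 rose, 12 fell of 15) and imprinted lncRNAs (0 rose, 5 fell of 5) were lower, both at adjusted p = 0.0267, but adjusted p = 0.529 with an estimated correlation and 0.111 after centring. Gm genes (31 rose, 365 fell; 0.0769; 0.848 with an estimated correlation, 0.0228 and higher after centring), differentiated-cell lncRNAs (0 rose, 5 fell of 8; 0.339), Rik genes (5 rose, 131 fell; 0.4), microRNA hosts (0 rose, 4 fell of 8; 0.685) and opposite-strand genes (1 rose, 17 fell of 38; 19 falls over the list alone; 0.972) did not pass. For opposite-strand genes the median lay below that of other lncRNAs (-0.75 against -0.65) while camera pointed up.

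In cytoplasm after SNRNP70 loss Gm28373 rose from 0.65 ± 0.23 to 17.7 ± 2.1 (log2 4.61, adjusted p = 0.000255). Snhg1 rose from 32.2 ± 2.7 to 87.6 ± 19 (log2 1.42, adjusted p = 0.00753). Snhg12 rose from 68.5 ± 6.2 to 252 ± 31 (log2 1.87, adjusted p = 0.00119). Gas5 rose from 54.9 ± 1.3 to 103 ± 6.4 (log2 0.91, adjusted p = 0.00983). Tsix rose from 0.633 ± 0.24 to 2.9 ± 0.22 (log2 2.09, adjusted p = 0.0154). In nucleoplasm Gm28373 rose from 0.483 ± 0.17 to 3.9 ± 0.22 (log2 2.82, adjusted p = 0.00129). Tsix rose from 3.11 ± 0.62 to 9.26 ± 0.95 (log2 1.56, adjusted p = 0.00213). Snhg1 rose from 51.3 ± 3.2 to 107 ± 3.9 (log2 1.06, adjusted p = 0.00257), while Gm38372 fell from 9.02 ± 1.5 to 1.4 ± 0.16 (log2 -2.60, adjusted p = 0.000609), and Neat1 (log2 -0.82, adjusted p = 0.0327) and Platr4 (log2 -1.15, adjusted p = 0.00559) fell. Cytoplasmic falls included Gm20703 (log2 -3.67, adjusted p = 0.0198) and 0610040B10Rik (log2 -3.11, adjusted p = 0.0478). Whole cells gained Gm45205 (log2 2.21, adjusted p = 0.00208) and Gm37115 (log2 1.79, adjusted p = 0.00252) and lost Gm42979 (log2 -2.34, adjusted p = 0.000665), Gm37303 (log2 -2.17, adjusted p = 0.00495) and Gm37893 (log2 -2.01, adjusted p = 0.00455). In limma cytoplasm gave 29 rises and 11 falls of 1089, with 19, 11, 10 and 14 calls without 0 h library 1 or 2 or 4 h library 1 or 2. Nucleoplasm gave 63 rises and 130 falls of 1209 (148 and 90 after centring; median -0.23 before it), with 92, 56, 120 and 114 without 0 h library 1 or 2 or 4 h library 1 or 2. Whole cells gave 67 rises and 82 falls of 1261, with 66, 97 and 69 without 0 h libraries 1 to 3 and 83, 58 and 98 without 4 h libraries 1 to 3.

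**Figure D2:**
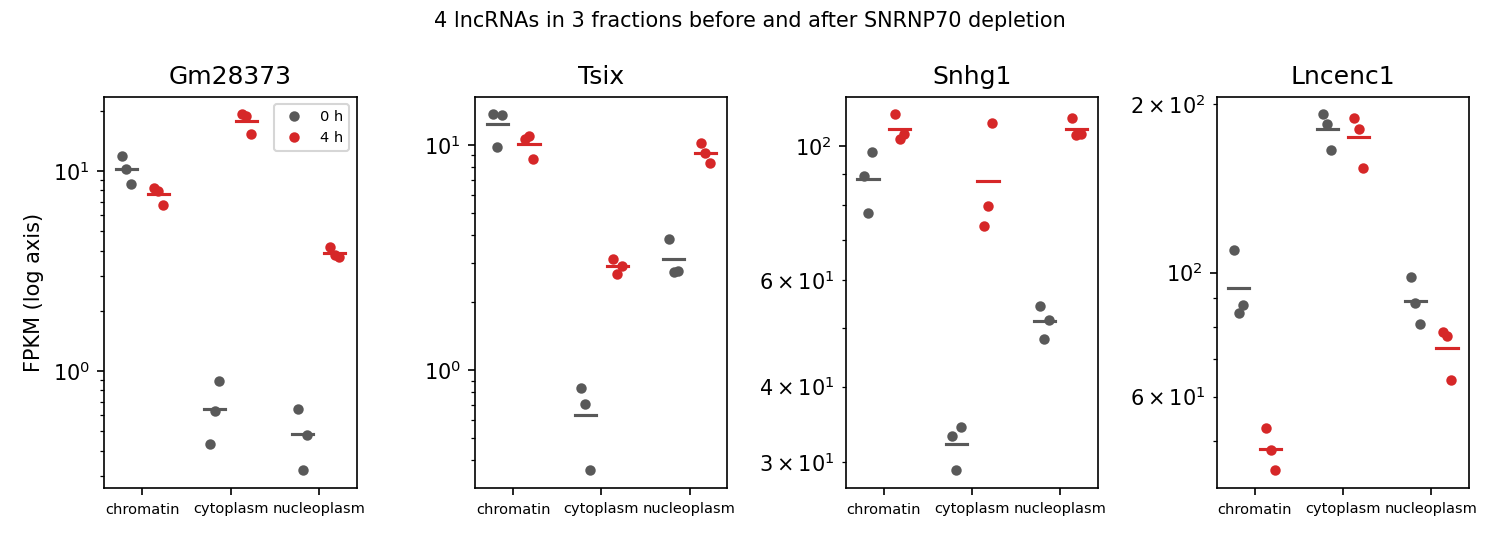
FPKM on a log axis of Gm28373, Tsix, Snhg1 and Lncenc1 in chromatin, cytoplasm and nucleoplasm of AID cells at 0 h (grey) and 4 h (red); dots are libraries and lines are means of 3. Gm28373 rose in cytoplasm (log2 4.61) as did Tsix (2.09) and Snhg1 (1.42), whereas Lncenc1 fell on chromatin (-0.95).

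The shift away from chromatin after SNRNP70 loss was largest for Gm28373 (log2 -4.12, adjusted p = 1.59e-07), whose chromatin level was 10.2 ± 1.6 at 0 h and 7.64 ± 0.78 at 4 h. Platr4 (log2 -2.37, adjusted p = 5.43e-05), Tsix (log2 -2.10, adjusted p = 0.000216), Pvt1 (chromosome 15, 62037986 to 62260215; log2 -1.33, adjusted p = 0.00109), Kcnq1ot1 (log2 -1.12, adjusted p = 0.00804), Firre (log2 -0.99, adjusted p = 0.00671), Meg3 (log2 -0.98, adjusted p = 0.00132) and Snhg1 (log2 -0.96, adjusted p = 0.00144) shifted too. For Lncenc1 (log2 -0.78, adjusted p = 0.00528) cytoplasm held 181 ± 13 at 0 h and 175 ± 18 at 4 h. Gas5 shifted as well (log2 -0.61, adjusted p = 0.0128, but 0.003 after centring, the opposite sign). Gm44033 (log2 -2.94, adjusted p = 0.00733), Gm43566 (log2 -2.79, adjusted p = 0.00102), Gm16008 (log2 -2.75, adjusted p = 0.00204) and Gm42929 (log2 -2.58, adjusted p = 0.000294) were the other largest, and Gm37943 (log2 1.14, adjusted p = 0.0466) and Gm43365 (log2 0.90, adjusted p = 0.0273) shifted towards chromatin, as did A430057M04Rik and a locus without a standard symbol, both taken up after their values were seen. Malat1 (log2 -0.52, adjusted p = 0.0784) and Neat1 (log2 -0.68, adjusted p = 0.114) did not pass. In limma 245 lncRNAs shifted away and 4 towards chromatin (median -0.57; 45 away and 23 towards after centring), with 151 and 148 calls without 0 h chromatin library 1 or 4 h chromatin library 3. Of the 245, 210 fell on chromatin, 36 rose in a soluble fraction and 14 did both; 148 fell on chromatin with no soluble call. By camera the ESC list (0 towards, 10 away of 18; 12 over the list alone; adjusted p = 0.000376), the imprinted list (0 and 4 of 5; 5 over the list alone; 0.0184) and Snhg-named genes (0 and 4 of 9; 6 over the list alone; 0.0368) lay lower, each at adjusted p = 0.481 with an estimated correlation. The nuclear-retained list (0 and 8 of 15; 11 over the list alone; 0.00292) lay lower and Gm genes (2 and 128; 0.0184) higher, both at adjusted p = 0.484 with an estimated correlation. After centring only the ESC list passed (0.00137), the imprinted (0.347), Snhg-named (0.935), nuclear-retained (0.111) and Gm lists (0.0588) being lost.

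U1 AMO and SNRNP70 loss, in different cells with separate controls, lowered many of the same lncRNAs on chromatin. Platr4, Nespas, Lncenc1, Neat1, Kcnq1ot1 and Dleu2 were in both sets, and Snhg12 rose in both. Among 1245 lncRNAs tested in both, 413 of 650 and 581 falls were shared, against 303.3 expected (one-sided Fisher exact p = 1.7e-36), and 12 rises of 63 and 40, against 2 (p = 1.81e-07). After centring 120 rises (47.7 expected) and 64 falls (24.2 expected) were shared. Changes correlated at 0.447 (Spearman 0.448) across genes, not independent replicates. For the shift 81 of 252 and 245 were shared among 1276, against 48.4 expected (one-sided Fisher exact p = 2.2e-08; 3 of 3 and 45 after centring, p = 4.11e-05), Gm28373, C230096K16Rik, Pvt1 and Lncenc1 included, with a correlation of 0.242 across genes. The sign was the same for 80.2% of lncRNAs, and for 59.3% after centring. Since 92.1% (U1 AMO) and 82.5% (AID) of lncRNAs shifted away from chromatin, equal signs would be common without any relation.

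In polyA RNA of chromatin Lncenc1 fell from 213 ± 11 to 72.8 ± 2.0 (log2 -1.55, adjusted p = 2.77e-06). Platr4 fell from 12.2 ± 2.3 to 2.45 ± 0.63 (log2 -2.28, adjusted p = 0.000136) after SNRNP70 loss, whereas Tsix rose from 38.1 ± 0.43 to 60.45 ± 0.8 (log2 0.67, adjusted p = 4.93e-05). Gm37914 rose from 1.55 ± 0.14 to 8.85 ± 0.41 (log2 2.45, adjusted p = 1.15e-05), then Gm45206 (log2 1.84, adjusted p = 2.33e-05), Gm45221 (log2 1.83, adjusted p = 7.00e-05), Gm27231 (log2 1.74, adjusted p = 0.00037) and Gm17501 (log2 1.71, adjusted p = 0.0001), and Nespas rose (log2 1.02, adjusted p = 0.000589). Gm44597 fell from 4.16 ± 0.49 to 0.337 ± 0.12 (log2 -3.32, adjusted p = 4.93e-05), then Abhd1 (log2 -3.13, adjusted p = 0.00022), Gm14286 (log2 -3.06, adjusted p = 9.18e-05), Gm37893 (log2 -3.0, adjusted p = 3.30e-05) and Gm43513 (log2 -2.97, adjusted p = 0.000129); Platr6 (log2 -2.59, adjusted p = 7.51e-05) and Dleu2 (log2 -1.32, adjusted p = 0.0001) fell too. Neat1 fell slightly (log2 -0.13, adjusted p = 0.0384) and Malat1 did not pass (log2 -0.09, adjusted p = 0.234), both with the opposite sign after centring (0.353 and 0.391). In whole cells Gm28373 rose from 0.1 ± 0.056 to 4.8 ± 0.38 (log2 4.65, adjusted p = 8.57e-06). Rab26os rose from 30.3 ± 5.6 to 158 ± 5.9 (log2 2.40, adjusted p = 3.61e-06). Gas5 rose from 138 ± 4.8 to 268 ± 18 (log2 0.95, adjusted p = 2.23e-05), and Malat1 (log2 0.63, adjusted p = 0.00205), Tsix (log2 1.81, adjusted p = 3.61e-06) and Snhg1 (log2 1.17, adjusted p = 2.03e-05) rose, while Gm37963 (log2 -2.67, adjusted p = 0.00141) and AI480526 (log2 -2.02, adjusted p = 0.000188) fell. In limma chromatin gave 109 rises and 448 falls of 1217 (median -0.37). After centring 232 of 433 calls were rises (median 0.11). Libraries did not overlap for 665 of the 1217, against 10% by chance for a single lncRNA, a share that a common library scale could also exceed. Whole cells gave 147 rises and 80 falls of 1135 (107 and 91 after centring), with 148, 146, 148 and 145 calls without 0 h library 1 or 2 or 4 h library 1 or 2. Chromatin falls in total and polyA RNA shared 302 lncRNAs of 473 and 382 among 941, against 192 expected (one-sided Fisher exact p = 1.87e-50), with a correlation of 0.708 across genes. After centring 93 falls (29.3 expected) and 133 rises (43.7 expected) were shared. Of the lists on chromatin only the ESC list passed camera (0 rose, 12 fell of 16; adjusted p = 0.00319, but adjusted p = 0.194 with an estimated correlation). After centring snoRNA hosts (0.00598), Snhg-named genes (0.0104) and cytoplasmic lncRNAs (0.0182) passed too, on the higher side, but without centring they had 0.509, 0.539 and 0.945 with an estimated correlation.

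The polyA shift, chromatin against whole cells, included Gm28373 (log2 -4.15, adjusted p = 2.14e-05), 2410003L11Rik (log2 -2.86), Gm12655 (log2 -2.40, adjusted p = 0.000514) and Gm16754 (log2 -2.38, adjusted p = 0.0212). Lncenc1 (log2 -1.22, adjusted p = 3.03e-07), Tsix (log2 -1.15, adjusted p = 4.31e-06), Snhg1 (log2 -0.97, adjusted p = 1.44e-05), Rab26os (log2 -1.75, adjusted p = 0.000263), Gas5 (log2 -0.75, adjusted p = 2.24e-05) and Malat1 (log2 -0.72, adjusted p = 0.00122) shifted away from chromatin. In limma 227 shifted away and 2 towards (median -0.49; 21 away and 9 towards after centring), the 2 being Gm26513 (log2 0.86, adjusted p = 0.0283) and Gm43258 (log2 1.15, adjusted p = 0.0328). Whole-cell values carry no named spike-in scale, so both scales meet in this contrast. Lists below other lncRNAs by camera were cytoplasmic lncRNAs (0 towards, 8 away of 10; 9 over the list alone; adjusted p = 3.78e-08), snoRNA hosts (0 and 9 of 12; 11 over the list alone; 2.76e-07), Snhg-named genes (0 and 7 of 9; 9 over the list alone; 2.76e-07) and the ESC list (0 and 10 of 16; 11 over the list alone; 0.000107). With an estimated correlation these kept adjusted p = 0.00333, 0.00333, 0.00333 and 0.0061. After centring snoRNA hosts did not pass (0.0628), while the other 3 did (0.00399, 0.0299 and 3.5e-05). Nuclear-retained lncRNAs passed on the lower side (0 and 8 of 15; adjusted p = 0.00369, and 0.0182 with an estimated correlation, but 0.61 after centring) although their median of -0.40 lay above the -0.49 of the others and their mean was -0.52. Gm genes lay higher (2 and 118; adjusted p = 0.0173, and 0.0142 with an estimated correlation).

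Newly made RNA, read as spike-in-scaled SLAM-seq signal from reads with T>C changes, fell on chromatin for Lncenc1, from 531 ± 41 to 194 ± 39.5 (log2 -1.43, adjusted p = 3.67e-05). Mirg fell from 183 ± 17 to 25.9 ± 2.2 (log2 -2.50, adjusted p = 2.53e-06). Firre fell from 159.6 ± 23 to 35.9 ± 12 (log2 -1.96, adjusted p = 5.28e-05). Gm43513 fell from 144 ± 22 to 5.59 ± 3.8 (log2 -3.52, adjusted p = 1.95e-06). Meg3 (log2 -1.13, adjusted p = 5.37e-05) and Malat1 (log2 -0.61, adjusted p = 0.00555) fell too, as did Kcnq1ot1 (log2 -0.54, adjusted p = 0.0154, but 0.023 after centring, the opposite sign). Gas5 rose from 469 ± 42 to 944 ± 207 (log2 0.98, adjusted p = 0.000541). Tsix rose from 1069 ± 221 to 1720.5 ± 173 (log2 0.70, adjusted p = 0.00359). Epb41l4aos rose from 89.3 ± 16 to 279 ± 79 (log2 1.53, adjusted p = 0.00018). Dancr rose from 59.4 ± 8.4 to 129.8 ± 19 (log2 1.03, adjusted p = 0.0025), with Gm21781 (log2 1.21, adjusted p = 0.00138), Gm44552 (log2 1.10, adjusted p = 0.00342) and Rab26os (log2 1.09, adjusted p = 0.00261); Snhg1 did not pass (log2 -0.04, adjusted p = 0.855, but 0.527 after centring, the opposite sign). Gm38248 (log2 -3.16, adjusted p = 1.64e-07), 9230114K14Rik (log2 -2.76, adjusted p = 1.64e-07) and 7330423F06Rik (log2 -2.52, adjusted p = 9.95e-07) were among the largest falls. In limma 24 rose and 142 fell of 423 (median -0.41; 96 and 65 after centring, median 0.15). With edgeR, 157 passed on the recovered reads, of which 156 were shared. Falls in total RNA and SLAM-seq shared 105 of 166 and 121 among 356, against 56.4 expected (one-sided Fisher exact p = 2.23e-29), with a correlation of 0.719 across genes. After centring 29 falls (9.4 expected) and 69 rises (29 expected) were shared. By camera the ESC list (0 rose, 7 fell of 9; 9 over the list alone; adjusted p = 0.0146, but adjusted p = 0.3 with an estimated correlation) and imprinted lncRNAs (0 rose, 4 fell of 5; 0.0209, but adjusted p = 0.3 with an estimated correlation) were lower, as were nuclear-retained lncRNAs (1 rose, 10 fell of 13; 0.0466, but adjusted p = 0.39 with an estimated correlation and 0.067 after centring). SnoRNA hosts (Gas5, Snhg17, Snhg20 and Epb41l4aos rose, Snhg14 fell, of 14) and cytoplasmic lncRNAs (Gas5, Epb41l4aos and Dancr rose, 0 fell, of 9) were higher, both at adjusted p = 0.0146, but adjusted p = 0.424 with an estimated correlation. Gm genes passed only after centring (0.0492, higher; 0.0902 before, and 0.424 with an estimated correlation).

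In soluble fractions the SLAM-seq signal of Gm28373 went from 22.9 ± 11 to 1107 ± 101 in cytoplasm (log2 5.22), that of Tsix from 345 ± 145 to 4108 ± 872 (3.61), Pvt1 from 58.3 ± 11 to 757 ± 114 (3.53) and Rab26os (chromosome 17, 24528251 to 24528744) from 701 ± 153 to 7724 ± 914 (3.46). The same 4 rose in nucleoplasm (log2 3.94, 3.09, 3.78 and 2.84), where Kcnq1ot1 (1.67) and Gas5 (2.09) also rose. Map2k3os (log2 -2.84, adjusted p = 0.00135) and Gm35082 (log2 -2.66, adjusted p = 0.00417) fell in cytoplasm. Gm28373 (log2 -3.56, adjusted p = 0.000161), Pvt1 (log2 -3.03, adjusted p = 0.000224), Tsix (log2 -2.65, adjusted p = 7.44e-07), Gm20342 (log2 -2.15, adjusted p = 0.00554), Rab26os (log2 -2.07, adjusted p = 3.71e-05) and Kcnq1ot1 (log2 -1.92, adjusted p = 0.000364) shifted away from chromatin, and Snhg1 (log2 -1.46, adjusted p = 0.000364), Malat1 (log2 -1.32, adjusted p = 0.00304), Neat1 (log2 -1.27, adjusted p = 0.00963) and Lncenc1 (log2 -1.05, adjusted p = 0.0207) shifted too. In limma cytoplasm gave 28 rises and 17 falls of 423 (29, 27 and 29 calls without libraries 1, 2 or 3 with IAA) and nucleoplasm 87 and 47 of 490 (76 and 67 after centring). The shift gave 24 away and 0 towards chromatin of 492 (median -0.52; 8 away and 3 towards after centring), with 15, 15 and 59 calls without chromatin library 3 without IAA, chromatin library 1 with IAA or cytoplasm library 2 without IAA. SLAM-seq and total RNA shared 16 of these shifts of 22 and 104 among 414, against 5.5 expected (one-sided Fisher exact p = 1.83e-06; 4 of 8 and 23 after centring, p = 0.000442). By camera the nuclear-retained list shifted below the others (0 towards, 6 away of 13; 8 over the list alone; adjusted p = 3.7e-05, but adjusted p = 0.147 with an estimated correlation). Per the labels chromatin was total RNA and the soluble fractions polyA RNA in this assay, so its shift mixes RNA classes.

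Pol II Ser5P peaks, the form near promoters, numbered 14809 at 0 h and 16216 at 4 h of SNRNP70 loss, and Ser2P peaks, the elongating form, 5915 and 7090. Ser5P peaks covered 24.87 Mb at 0 h and 29.74 Mb at 4 h, with median widths of 1223 and 1336 bp. Ser2P peaks covered 8.801 and 12.41 Mb, with median widths of 1023 and 1179 bp. Of Ser5P peaks at 0 h 75.8% overlapped one at 4 h, and of Ser2P peaks 57.0%, while 42.1% of Ser2P peaks at 0 h overlapped a Ser5P peak. At 50% reciprocal overlap these were 61.0%, 30.2% and 18.1%. Of the peaks at 4 h, 66.7% (Ser5P) and 42.7% (Ser2P) overlapped one at 0 h. The highest-scored Ser2P peak at 0 h lay on chromosome 1, 88423998 to 88430980 (mm9), and that at 4 h on chromosome 7, 26026062 to 26033958. With 1 library per list these differences were not tested.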

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

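The split comparisons, the tests of explanations and the direct contrast of U1 with U2 AMO on chromatin were chosen only after the results had been seen, whereas the limma comparisons and centring were chosen before.

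The fall of lncRNAs on chromatin had 715 calls after U1 AMO against 0 in the highest of the other splits, and 628 after SNRNP70 loss against 1, the real grouping being 1 of 10 splits in each case. So few splits cannot give a share under 0.05. The other splits mixed treated with control libraries, which lowers their calls wherever the groups differ. A library scale factor alone would leave no calls after centring if all values lay far above the pseudocount. After centring 371 remained for U1 AMO (highest other split 0) and 475 for SNRNP70 loss (highest other 1). On the scale used, the lncRNAs thus differed from one another in their changes. Part of this may come from the pseudocount, which makes low values move less than high ones under the same factor. Centring removed the common fall itself, leaving 226 rises and 145 falls after U1 AMO. These calls therefore do not decide whether a scale factor caused the common fall. Low values near the pseudocount would leave the best-measured lncRNAs unchanged, yet the median of the best-measured part of the lncRNAs by mean was -0.76 after U1 AMO (upper quartile -0.07). A difference in the authors' spike-in scale between groups could still account for the common fall: the whole-cell median of -0.21 comes from values on another scale and does not decide it. U2 AMO, the biological comparison in the design, gave a median of -0.14 on chromatin and 63 falls.

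The rise of lncRNAs in nucleoplasm after U2 AMO had 221 calls against 1 in the highest other of 10 splits (the real one being 1). A scale factor alone would leave no calls after centring if all values lay far above the pseudocount, and 132 remained (highest other 1). The control medians here, 0.39 to 0.59, were close to the pseudocount of 0.2, so a scale factor could leave calls as well. Since centring removes any common rise, these calls do not decide its cause. A difference in spike-in scale might account for part of it and stays open: 95 rises and 37 falls remained, but centring sets the median by construction. No biological explanation was tested.

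The lncRNAs that rose in both soluble fractions numbered 39 after U1 AMO, 15 after SNRNP70 loss in total RNA and 24 in SLAM-seq, 23 of them tested on chromatin. Release from chromatin alone predicts lower chromatin levels for them, but their median change on chromatin was 0.73 after U1 AMO (lower quartile 0.28), 0.21 after SNRNP70 loss (-0.29) and 0.70 in SLAM-seq (0.22), against -0.82, -0.66 and -0.46 for the others. A scale factor of the soluble fractions after U1 AMO is unlikely to be the cause, as the median of all lncRNAs in cytoplasm was -0.20. More RNA made or less decay could give rises in all fractions, though after SNRNP70 loss in total RNA only 3 of the 15 rose on chromatin and 2 fell, and neither was tested.

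Only named lncRNAs and list members were searched here, for calls on chromatin in opposite directions with no overlap of libraries. For U1 and U2 AMO, each against control AMO, 5 met this. The direct limma contrast gave Gm45073 (difference -3.31, from -0.80 and 2.51, adjusted p = 5.55e-06), E230020D15Rik (-3.24, from -1.12 and 2.12, 6.46e-06), Gm15344 (-2.83, from -1.25 and 1.58, 5.55e-06), Gm44553 (-2.34, from -0.94 and 1.39, 7.58e-05) and Gas5 (-1.84, from -0.69 and 1.15, 3.38e-05). The same U1 and U2 AMO libraries served for the search, so these low p-values follow from it and are no separate support. Gm45073 and Gas5 after U1 AMO had the opposite sign after centring. Every library moved one way after U1 AMO and the other way after SNRNP70 loss for Gm38336 (difference -2.75; -1.49 and 1.26), Gm45205 (-2.30; -1.0 and 1.30) and Gm12737 (-2.14; -0.87 and 1.27), differences that were not tested. Total and polyA RNA of chromatin went opposite ways for Nespas (-3.02; -2.0 and 1.02), Gm38336 (1.72; 1.26 and -0.46) and Snhg12 (1.52; 1.31 and -0.20), again not tested. The polyA values of Gm38336 and Snhg12 had the opposite sign after centring. Dancr was lower in total RNA and higher in SLAM-seq (-1.74; -0.72, opposite in sign after centring, and 1.03), not tested.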

How the results depend on the processing

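Of the tests in this part the 2 direct contrasts on chromatin were chosen only after the results had been seen. Of 1034 results for named lncRNAs 788 passed the threshold, 435 of them in every setting and 571 when left-out libraries and centring were set aside. Apart from the standing set, lncRNAs were named only if they passed, so 788 is not a rate of passing. The opposite sign was taken by 42, all after centring, counted only where at least 1 of the 2 fits passed. Centring subtracts 1 value per library, so such changes of sign follow from it for lncRNAs near the median and leave the cause untested. A stricter filter leaves fewer lncRNAs to test, and what read depth limits was not tested.

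Centring each library left, in calls, 371 for U1 AMO, 291 for U1+U2 AMO on chromatin, 247 for U1 AMO and 132 for U2 AMO in nucleoplasm. Shifts fell to 13 (U1 AMO), 3 (U2), 13 (U1+U2), 2 (U1 against U2), 68 (AID), 11 (SLAM-seq) and 30 (polyA), with overlaps of shifted lncRNAs of 3 (U1 AMO and AID) and 1 (U1 and U2 AMO). Signs turned on chromatin of U1 AMO for Malat1 0.137, Meg3 0.432, Rian 0.648, Firre 0.068, Gas5 0.15, Snhg1 0.805, Dancr 0.163, Halr1 0.12 and Mir17hg 0.381, and of U1+U2 AMO for Malat1 0.217, Meg3 0.473, Rian 0.559, Firre 0.111, Snhg8 0.13, Dancr 0.119, Snhg5 0.219 and Mir17hg 0.281. On AID chromatin Meg3 0.049, Rian 0.103, Tsix 0.463 and Dancr 0.027 turned, in polyA RNA Malat1 0.391, Neat1 0.353, Meg3 0.388, Firre 0.429, Tug1 0.339, 2900097C17Rik 0.124, Snhg5 0.139, Snhg12 0.278, Halr1 0.119 and Mir17hg 0.306, and in SLAM-seq Kcnq1ot1 0.023 and Snhg1 0.527. Among shifts Kcnq1ot1 0.018 (U1 AMO), Tug1 0.552, Gas5 0.003 and Snhg15 0.031 (AID), and Neat1 0.218, Meg3 0.224, Rian 0.083 and Mir17hg 0.092 (polyA) turned, and Lncenc1 was -0.474 in the control AMO baseline.

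A stricter filter gave 423 (U1 AMO), 65 (U2), 386 (U1+U2), 362 (AID) and 103 (SLAM-seq) calls on chromatin and 140 for the U1 AMO shift. No filter gave 16 for SLAM-seq cytoplasm. One fit of all fractions gave 258, 125 and 313 for cytoplasm of U1, U2 and U1+U2 AMO, 140 for AID cytoplasm, and 78 and 98 for SLAM-seq chromatin and cytoplasm. A pseudocount 10 times larger gave 164 and 31 for U2 AMO chromatin and cytoplasm, shifts of 408 (U1 AMO), 61 (U2), 293 (U1+U2), 179 (U1 against U2), 473 (AID) and 63 (SLAM-seq), and overlaps of 232 (U1 AMO and AID) and 48 (U1 and U2 AMO). One 10 times smaller gave shifts of 130, 12, 47, 3 and 165 (AID) in the same order and overlaps of 43 and 10. Without trend U2 AMO cytoplasm gave 2, AID cytoplasm 3, SLAM-seq cytoplasm 10, SLAM-seq nucleoplasm 87, the U1 against U2 shift 6 and the SLAM-seq shift 13. Against cytoplasm alone shifts were 116 (U1 AMO), 57 (U1+U2) and 95 (U1 against U2), and against nucleoplasm alone 57 (U2), 56 (U1+U2), 0 (U1 against U2), 70 (AID) and 13 (SLAM-seq). On chromatin alone U1 against U2 AMO gave 570, chosen after seeing the data, and calls on chromatin shared 413 falls (U1 AMO and AID) and 60 (U1 and U2 AMO). With an estimated correlation 6 of 34 list calls remained.

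With a replicate block U2 AMO gave 189 calls on chromatin, 29 in cytoplasm and 11 shifts, U1 against U2 30 shifts, AID whole cells 83 calls and the overlap of U1 and U2 AMO 10. Residuals of libraries with the same number correlated over 0.1 in every pair in 7 of 21 comparisons, all from the AMO set. In 11 of the 21, again all from the AMO set, every treated library correlated best with the library of its own number. The AMO libraries thus look paired by number, which the main fits leave out. For named lncRNAs 26 results no longer passed with the block and 26 passed only with it. Among lists the block ended the calls of ESC lncRNAs after U1+U2 AMO (0.0922) and of nuclear-retained lncRNAs on SLAM-seq chromatin (0.06). It made calls of snoRNA hosts in the AID shift (0.0421, but 0.484 with an estimated correlation and no block) and of cytoplasmic lncRNAs in the SLAM-seq shift (0.0356). It changed no other list call and moved no other count by over 1.5 times. Pol II overlap at 50% reciprocal was 30.2% for Ser2P and 61.0% for Ser5P, for peaks of higher score 65.0% and 80.8%, and merged within 1 kb 57.5% and 77.7%.

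Leaving out 1 library at a time gave these ranges of calls, where a lone whole-cell control is assumed to vary like the other groups. U1 AMO: whole cells 70 to 152, chromatin 603 to 664, cytoplasm 44 to 75, nucleoplasm 124 to 161, shift 104 to 309. U2 AMO: 0 to 35, 40 to 93, 0 to 15, 125 to 255, and shift 0 to 11. U1+U2 AMO: 71 to 122, 547 to 665, 41 to 80, 92 to 157, and shift 7 to 148. AID: 58 to 98, 486 to 604, 10 to 31, 56 to 132, and shift 148 to 260. PolyA RNA: whole cells 145 to 175, chromatin 459 to 544, shift 155 to 221. SLAM-seq: chromatin 115 to 176, cytoplasm 27 to 55, nucleoplasm 95 to 115, shift 15 to 59. U1 against U2 AMO shift 0 to 31, U1+U2 against U1 AMO on chromatin 0 to 0, and baselines 830 to 893 (AMO) and 974 to 1027 (AID).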

Other observations

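The split comparisons and the tests of lncRNAs that rose in both soluble fractions were chosen only after the results had been seen, whereas the limma comparisons were chosen before.

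Rab26os (ENSMUSG00000093565.1), an opposite-strand gene of 494 bp, gained in every soluble fraction after SNRNP70 loss: from 48.0 ± 7.2 to 129 ± 27 (log2 1.42, adjusted p = 0.00983) FPKM in cytoplasm and log2 1.47 in nucleoplasm of total RNA. Dancr fell on chromatin of U1 AMO cells (log2 -0.68, adjusted p = 0.0331; 0.163, the opposite sign, after centring) and shifted away from it after U1 AMO (log2 -1.63, adjusted p = 0.00913) and SNRNP70 loss (log2 -1.54, adjusted p = 0.00113), rising in cytoplasm (log2 1.09, adjusted p = 0.0198). Pvt1 fell on AID chromatin from 22.0 ± 4.1 to 12.8 ± 2.9 (log2 -0.79, adjusted p = 0.0117) and rose in cytoplasm (log2 0.93, adjusted p = 0.022). Snhg6 fell on chromatin of AID cells from 28.4 ± 3.9 to 13.9 ± 1.1 (log2 -1.02, adjusted p = 0.000746), unlike Snhg12 and Snhg3.

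Among lncRNAs that rose in both soluble fractions after U2 AMO, 5 in all, 3 rose on chromatin and 0 fell (limma), with a median of 0.69. After U1+U2 AMO there were 26, of which 12 rose and 1 fell on chromatin (median 0.55). After U1 AMO 24 of 39 rose and 1 fell, after SNRNP70 loss in total RNA 3 of 15 rose and 2 fell, and in SLAM-seq 11 of the 23 tested on chromatin rose. A few transcripts took much of the lncRNA signal: in AMO whole cells 1 entry, AY036118, held up to 63.63% of the summed values (U1 AMO library 2). The highest share in U1 AMO whole-cell library 1 was 21.57%, so shares differed between replicates. Whole-cell values have no named spike-in scale, and what the uneven shares do to other values was not tested.

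As a check against chance, the real grouping was compared with other splits of the same libraries, and in each comparison of 3 against 3 libraries it was 1 of 10, too few for a share under 0.05. Every other such split mixed treated with control libraries. Where the groups differ, this widens the spread and lowers the calls, so low counts in these splits are no separate support. Calls for the real grouping and for the highest other split were 91 and 0 (U1 AMO cytoplasm), 162 and 1 (U1 AMO nucleoplasm), 98 and 0 (U2 AMO chromatin), 16 and 0 (U2 AMO cytoplasm), 666 and 0, 102 and 0, and 168 and 0 (U1+U2 AMO chromatin, cytoplasm and nucleoplasm). For the AID line they were 149 and 1, 40 and 1, and 193 and 0 (whole cells, cytoplasm, nucleoplasm), for polyA RNA 227 and 0 and 557 and 0 (whole cells, chromatin), and for SLAM-seq 166 and 0, 45 and 0, and 134 and 0 (chromatin, cytoplasm, nucleoplasm). Shifts gave 253 and 0 (U1 AMO), 7 and 0 (U2), 107 and 0 (U1+U2), 12 and 0 (U1 against U2), 249 and 0 (AID), 24 and 0 (SLAM-seq) and 229 and 0 (polyA). For the control AMO baseline 4 of 100 splits, the real one included, gave at least its 884 calls, the highest being 1083 for the split that set the 3 nucleoplasm libraries apart. For the AID baseline the real grouping was the only 1 of 100 to reach 1021 calls; the highest other, 969, kept the chromatin libraries together and mixed cytoplasm with nucleoplasm.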
